A study of Drosophila melanogaster with 34 samples.

How the data were processed

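Poly(A) RNA of 34 single Drosophila embryos was sequenced on libraries made with the TruSeq v2 chemistry, with embryos of 2 genotypes under 4 light windows and 1 group of CRY2-ZLD embryos without light. The deposited table holds, per gene, counts for each library that were not normalised. They were made by the authors with featureCounts v1.5.3 and the FlyBase r6.20 annotation, and per the file headers in 1 run over filtered alignments with no strand, paired-end or multi-mapping option. Its other numeric column, deposited with the counts, holds the summed exon length in bases (other unit), which no comparison used. Per the labels the authors also used Trimmomatic 0.36, HISAT2 2.1.0 and DESeq2 1.14.1 on assembly dm6. The values were checked to be whole numbers, and no pair of the 34 columns was identical. The lowest chi-square per degree of freedom between replicates was 33.4. Symbols and positions came from the Ensembl annotation of the same assembly, which named 17360 of the 17491 genes, and 131 had no symbol. No genome sequence was used here.

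Of the 17491 genes, 2887 had 0 counts in every library. Genes were tested when filterByExpr with a minimum count of 10 kept them by group, which left 9519 genes holding 99.98% of all counts. Library totals of 4382299 to 41210334 counts set the precision of each value, and the spread between embryos was larger than counting error. Where a group's libraries together had 0 counts of a gene, a floor of 3 counts over the group gave the lower bound of its fold, and with 1 to 3 counts the ratio is given with its 95% counting interval. Both cover counting error only, since reads without molecular identifiers are not independent molecules. CPM are given as mean ± SD over libraries, from TMM-scaled library sizes.

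Counts were fitted in R 4.3.3 with edgeR 4.0.16 (TMM scaling, estimateDisp, glmQLFit and glmQLFTest) in 1 model with a mean for each of the 9 groups. Groups of 3 or 4 embryos thereby share an estimate of the spread (common dispersion 0.197, prior degrees of freedom 5.47, residual degrees of freedom 25). P-values were adjusted by Benjamini and Hochberg over the genes tested in each comparison, with a threshold of 0.05. The comparisons were CRY2-ZLD against wild type within each of the 4 light windows, lit against unlit CRY2-ZLD in each window, unlit CRY2-ZLD against wild type in the same library set. There were also 4 tests of the difference between windows (NC10-14 against NC13-14, NC10-14 against NC10-12, NC10-12 against NC14 and NC13-14 against NC14). Wild type NC10-14 against wild type NC13-14, and the genes that differ from both controls, were added after the data were seen. Overlaps of calls between windows were tested with Fisher's exact test across genes.

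Before the data were examined, the groups, comparisons, tests, alternatives, gene lists and the rule for naming genes were fixed. The 21 lists were cellularization and early cell cycle, X counting and sex determination, gap and head gap, pair-rule, segment polarity, dorsal ectoderm and amnioserosa, neurogenic ectoderm and midline, mesoderm, terminal and gut, hox, and Bearded and E(spl). They further held maternal RNAs of oocyte and egg, maternal activators and chromatin binders, cytosolic ribosomal proteins, heat shock response, oxidative stress and light damage, p53 and apoptosis, follicle cells and yolk protein (another tissue), differentiated tissues of later embryos, pole cells, and embryo sex readouts. Some genes stand in several lists (zld and bcd, for example). Each list was tested in each comparison with camera in limma 3.58.1 (preset inter-gene correlation of 0.01), adjusted over the lists, and again with a correlation estimated from the data and with fry. Counts of members are given as called over all genes tested and adjusted over the list alone.

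The rule named a panel of early genes in each comparison (zld, His2Av, nullo, Sry-alpha, bnk, slam, Z600, halo, sna, twi, sog, zen, gt, Kr, kni, hb, eve, ftz, sc and Sxl). It added the 6 called genes with the largest decrease and the 4 with the largest increase among those with a mean of at least 10 CPM in the higher group whose libraries did not overlap between the groups. It also took from each list up to 4 members with the smallest p. The genes Blimp-1, Mdh2, Cyp4e2, ush and smg were also followed in comparisons outside the rule, chosen after their values were seen.

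The alternatives were DESeq2 size factors in the edgeR fit, scaling by the summed counts of cytosolic ribosomal protein genes, no filter on low counts, and a mean of at least 5 CPM. Further alternatives were DESeq2 1.42.0 (Wald test), limma-voom, a fit of only the libraries compared, a replicate block (alone, and with only the groups compared), thinning of each library to the smallest total (seed 20181), stricter thresholds, and leaving out each library in turn. Chosen after the data were seen were a term for the 2 parts of the first library set, leaving out mitochondrial and ribosomal RNA genes, leaving out 5 libraries, DESeq2 and limma-voom with ribosomal protein scaling (for the difference between NC13-14 and NC14), and other wild-type references for the unlit embryos (NC13-14 alone, NC10-14 alone and all 4 groups). Library sets were read from the numbers in the library names, which run from 1 to 18 in the first set and from 1 to 8 in the other 2 sets. Suffixes 1 to 10 and 11 to 18 of the first set differ in their share of mitochondrial ribosomal RNA. Whether equal replicate numbers pair embryos was checked on gene residuals: of 15 pairs the correlations ran from -0.11 to 0.28, 5 were over 0.1 and 5 were highest with their own number, so no pairing was assumed. The pipeline was tested on simulated data made from the real counts.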

Results

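Poly(A) RNA was sequenced from single Drosophila embryos that expressed a red fluorescent His2Av marker and were collected 30 minutes into nuclear cycle 14 (NC14). Zelda, the product of zld, is a DNA-binding factor that opens chromatin for the first zygotic transcription. In CRY2-ZLD embryos it is fused to CRY2, a plant photoreceptor that clusters under blue light, and this switches the fusion protein off while the light is on. CRY2-ZLD and wild-type embryos received 488 nm light during NC10-14, NC10-12, NC13-14 or NC14, and 1 further group of CRY2-ZLD embryos received none. The 34 libraries formed 9 groups, of 3 embryos in the NC10-14 groups of both genotypes and of 4 in the other 7. No wild-type embryos without light were used here. Library totals ran from 4382299 to 41210334 counts. The lowest total was in wild type NC13-14 replicate 4, where 8.53% of counts were nuclear ribosomal RNA, and the next was 13846445.

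The library names put the NC10-14, NC13-14 and unlit groups in 1 set, and the NC10-12 and NC14 groups in a set each. Within the first set the mitochondrial large ribosomal RNA took 6.03 to 7.77% of counts in 10 libraries and 0.580 to 3.07% in the other 8. In the NC10-12 and NC14 sets it took 6.17 to 8.51% and 6.04 to 10.6%. Each part of the first set held 2 libraries of every group of 4, or 2 and 1 of the NC10-14 groups, and no comparison was run within a part alone. The fit with the 2 parts as a term is given beside the counts of those groups. After the data were seen, 5 libraries were judged to stand apart: wild type NC10-14 replicate 2, CRY2-ZLD NC10-12 replicates 3 and 4, wild type NC14 replicate 3 and wild type NC13-14 replicate 4. All log2 changes below are CRY2-ZLD minus wild type unless said otherwise, ± SE, with p-values adjusted over the 9519 genes tested. Of the 21 gene lists, 20 had enough tested members for a test as a list. A list's p is from camera with its preset correlation, followed by the same test with an estimated correlation.

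The zld transcript itself (FBgn0259789, chromosome X, 19766465 to 19783548, minus strand) stood at 873 ± 144 CPM (read count scaled to library size; SD, n = 3) in wild type NC10-14 and at 970 ± 120 (n = 3) in CRY2-ZLD NC10-14. Its difference did not pass at NC10-14 (0.15 ± 0.32), nor at NC13-14 (-0.27 ± 0.27) and NC14 (-0.22 ± 0.27), the last 2 of which turned to 0.02 and 0.29 with scaling on the ribosomal protein genes. At NC10-12 zld rose by 1.35 ± 0.28 (adjusted p = 0.000377), from 470 ± 32.6 to 1203 ± 618 CPM (n = 4 each), and without the 5 libraries the difference was 0.69 (adjusted p = 0.0888). The marker gene His2Av, a histone variant, differed by -0.29 ± 0.21 at NC10-14, -0.12 ± 0.18 at NC10-12, -0.07 ± 0.18 at NC13-14 and 0.20 ± 0.18 at NC14. None of these passed, and ribosomal protein scaling turned the NC10-12 and NC13-14 values to 0.09 and 0.13. Leaving out CRY2-ZLD NC13-14 replicate 1 turned the NC13-14 value to 0.01, and leaving out wild type NC14 replicate 3 turned the NC14 value to -0.03. Sry-alpha, a cellularization gene, had 0 counts in every library and shares 3300 exon bases with Sry-beta in the annotation, so it was not assessed.

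**Figure D1:**
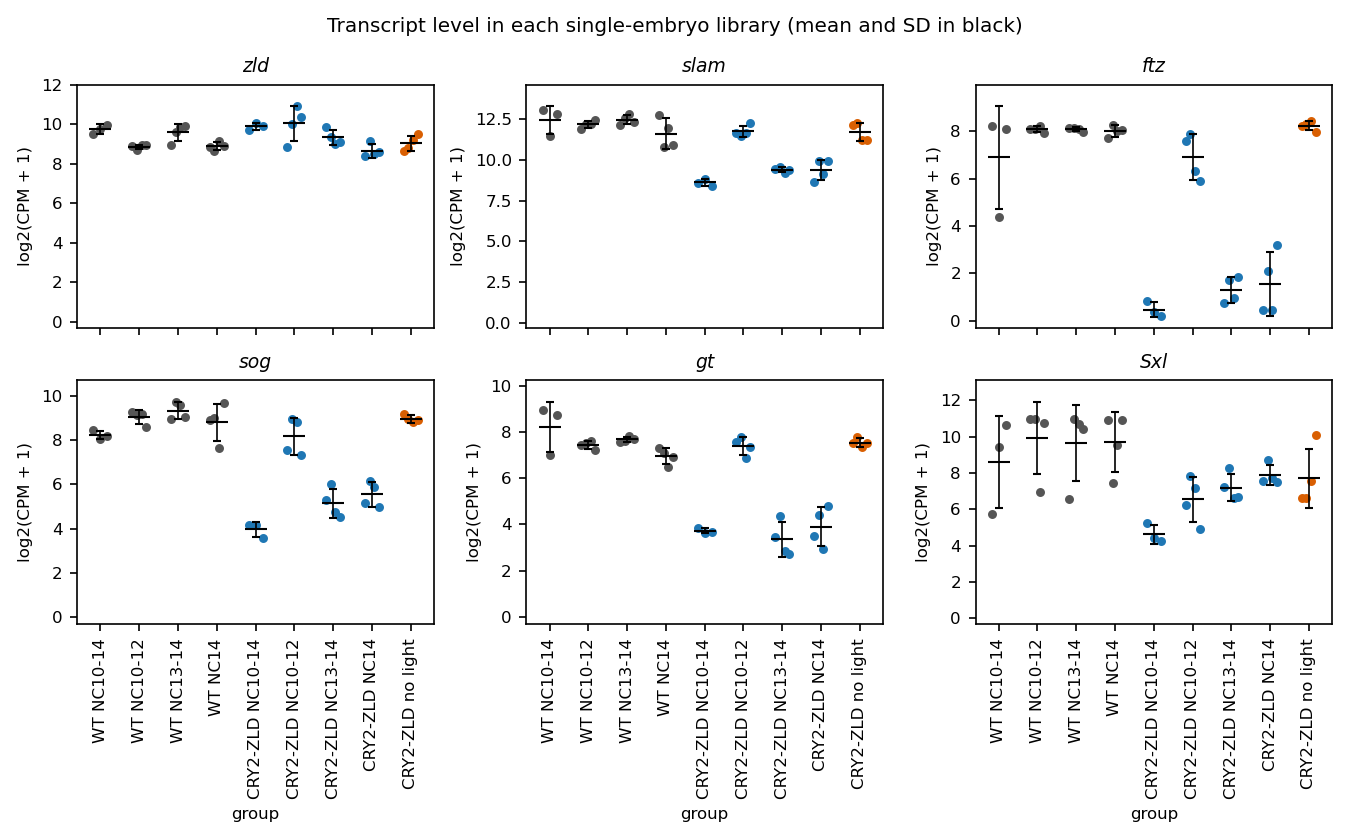
Levels of zld, slam, ftz, sog, gt and Sxl in each of the 34 single-embryo libraries, as log2(CPM + 1) on the y axis and the 9 groups on the x axis; points are libraries, and bars are the group mean ± SD. In the NC13-14 groups ftz averaged 272 CPM in wild type and 1.61 in CRY2-ZLD, and in the NC10-12 groups 274 and 142.

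Light throughout NC10-14 asked which transcripts depended on Zelda over the whole of the first zygotic wave. The cellularization gene slam (FBgn0043854, chromosome 2L, 6372388 to 6377284), which guides membrane growth between nuclei, fell from 6228 ± 3046 to 398 ± 64.1 CPM (SD, n = 3 each; log2 -3.97 ± 0.45, adjusted p = 8.67e-08). The pair-rule gene ftz (FBgn0001077, chromosome 3R, 6864324 to 6866244) fell from 197 ± 154 to 0.393 ± 0.319 CPM (-8.95 ± 1.04, adjusted p = 1.34e-07). Every one of the 9 tested cellularization and early cell cycle genes fell, also when adjusted over the list alone (median -3.37, adjusted p = 1.52e-21; adjusted p = 0.000634 with an estimated correlation). Among them were bnk (-6.62 ± 0.86), a regulator of the actin network around furrows, halo (-4.82 ± 0.56), which directs lipid droplet transport, Nrt (-3.77 ± 0.26), which codes for a membrane adhesion protein, and nullo (-3.37 ± 0.84). Of 8 genes for X counting and sex determination 7 fell, and 7 adjusted over the list alone, with upd1 at -9.31 ± 0.95, sc at -6.26 ± 0.86 and sisA at -5.79 ± 0.75, all X-linked activators of Sxl, the switch gene of female development. The list had a median of -4.71 and adjusted p = 1.16e-09 (0.000634 with an estimated correlation). Without light sc (-4.60) and nullo (-6.28) were also lower than in this wild type. Sxl (FBgn0264270, chromosome X, 7074550 to 7098053) fell by 4.96 ± 1.20 (adjusted p = 0.00388), but with limma-voom it was -4.11 (adjusted p = 0.0831).

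Of the 16 dorsal ectoderm genes 11 fell and 1 rose at NC10-14, 11 and 3 adjusted over the list alone (median -3.60, adjusted p = 2.11e-11; adjusted p = 0.00212 with an estimated correlation). The BMP pathway genes tld (-8.03 ± 0.66), tsg (-5.93 ± 0.46) and dpp (-4.13 ± 0.47) and the homeobox gene zen (-5.47 ± 0.68) were among them. Of the 10 tested Bearded and E(spl) genes, which tune Notch signalling, 5 fell and 1 rose, 7 and 1 adjusted over the list alone, with Ocho at -5.94 ± 0.52. The list had adjusted p = 2.89e-08 (0.00543 with an estimated correlation). The 5 embryo sex readouts held 3 that fell, and 3 adjusted over the list alone, with the dosage compensation RNA lncRNA:roX1 at -4.38 ± 0.55. The list had adjusted p = 0.0085 (0.0295 with an estimated correlation). Pair-rule genes fell in 8 of 10 and rose in 1, also when adjusted over the list alone, with hry (hairy) at -6.28 ± 0.72 and eve at -4.59 ± 0.51. Pair-rule genes as a list had adjusted p = 5.51e-08, and adjusted p = 0.0822 with an estimated correlation. Gap genes fell in 7 of 14, with gt at -4.85 ± 0.49, Kr at -2.66 ± 0.41 and kni at -2.53 ± 0.49, and 8 fell and 1 rose adjusted over the list alone. Gap genes as a list had adjusted p = 3.61e-06, and adjusted p = 0.131 with an estimated correlation. Neurogenic ectoderm genes fell in 6 of 12, and 6 adjusted over the list alone, with sog, a BMP inhibitor, at -4.34 ± 0.48. The list had adjusted p = 0.00117 (0.242 with an estimated correlation). Terminal and gut genes fell in 4 of 6, and 4 adjusted over the list alone, with tll at -5.89 ± 0.85 (adjusted p = 0.00117; adjusted p = 0.136 with an estimated correlation). Ribosomal protein genes, of which 1 fell and 1 rose of 87, and 1 fell adjusted over the list alone, were called as a list. The member that fell was RpS5b (-0.97 ± 0.22, and -0.73 with scaling on the list itself). It was also lower in CRY2-ZLD without light, at -1.0 ± 0.17 against wild type NC10-14 and NC13-14 averaged. Ribosomal protein genes as a list had a median of -0.26 and adjusted p = 0.0085, and adjusted p = 0.783 with an estimated correlation.

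Of the 15 mesoderm genes 4 fell and 2 rose at NC10-14, and the list was not called (adjusted p = 0.227). The hox genes (1 lower and 3 higher of 8, adjusted p = 0.638) and segment polarity genes (1 lower and 2 higher of 8, adjusted p = 0.384) were not called as lists either. Among the mesoderm genes the mesoderm determinant sna fell by 4.75 ± 0.88. The mesoderm determinant twi passed (-1.94 ± 0.57, adjusted p = 0.0192) but not without CRY2-ZLD replicate 4 (-1.51, adjusted p = 0.122), without wild-type replicate 4 (-1.28, adjusted p = 0.185) or with ribosomal protein scaling (-1.50, adjusted p = 0.0973). The gap gene hb differed by -1.68 ± 0.60 and did not pass (adjusted p = 0.0532). Among transcripts that rose were Xrp1, a transcription factor of the DNA damage and stress response (3.23 ± 0.55), and mid, a T-box gene of the later epidermis (5.74 ± 1.06). Xrp1 was higher in all 4 windows and also without light (1.29 ± 0.39, adjusted p = 0.0125, against wild type NC10-14 and NC13-14 averaged). In lit against unlit CRY2-ZLD at NC10-14 it was at 2.33 ± 0.48 (adjusted p = 0.000277). Outside the lists, phtm, an ecdysone synthesis enzyme, had 1 count over the 3 CRY2-ZLD libraries and was 1980-fold lower (95% counting interval 355 to 78200). The receptor gene mthl8 was at least 468-fold higher, with 0 counts over the 3 wild-type libraries and a floor of 3 counts for the group. It was also higher without light, by 11.05 ± 1.54 against the same averaged wild type, so its difference is not tied to light. Both NC10-14 groups also carried the maternal transcript of smg, an RNA-binding repressor that clears maternal RNA, at high levels. It stood at 1498 ± 451 CPM in wild type and 2307 ± 1286 in CRY2-ZLD (n = 3 each), against 236 ± 99.0 in wild type NC13-14 (n = 4).

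Over all genes tested, 722 fell and 744 rose at NC10-14, and 741 and 697 with the 2 parts of the library set as a term. The higher count was 425 without wild-type replicate 1 and 404 without wild-type replicate 4, DESeq2 gave 1127 higher, and a fit of only these 6 libraries gave 393 lower and 281 higher. Scaling on the ribosomal protein genes shifted the median of all genes by 0.28 and gave 446 lower and 807 higher, so that 35.6% of the calls were lower against 49.2%.

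Light during NC13-14 alone left Zelda active until the last fast cycle. The gene slam again fell from 5857 ± 1180 to 681 ± 74.8 CPM (SD, n = 4 each; log2 -3.10 ± 0.38, adjusted p = 2.68e-07) and ftz from 272 ± 14.9 to 1.61 ± 0.970 CPM (-7.40 ± 0.82, adjusted p = 5.32e-08). Of 16 dorsal ectoderm genes 12 fell and 1 rose, also when adjusted over the list alone, with Doc2, a T-box gene of the amnioserosa, at -8.19 ± 0.98 and tld at -6.97 ± 0.54. Dorsal ectoderm genes as a list had a median of -2.39 and adjusted p = 5.77e-11, and adjusted p = 0.0073 with an estimated correlation. Pair-rule genes fell in 8 of 10, and adjusted over the list alone 8 fell and 2 rose, with hry at -6.62 ± 0.63 and eve at -3.46 ± 0.42. Pair-rule genes as a list had adjusted p = 3.27e-10, and adjusted p = 0.0451 with an estimated correlation. Of the 9 cellularization genes 8 fell, and adjusted over the list alone 8 fell and 1 rose, with bnk at -3.87 ± 0.65 and Nrt at -3.14 ± 0.22. Cellularization genes as a list had a median of -1.73 and adjusted p = 5.66e-09, and adjusted p = 0.0437 with an estimated correlation. The exception, nullo, differed by 1.48 ± 0.71 and did not pass. X counting genes fell in 5 of 8, and 7 adjusted over the list alone (adjusted p = 5e-07; adjusted p = 0.00292 with an estimated correlation), with upd1 at -7.08 ± 0.75.

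The remaining called lists at NC13-14 lost their call with an estimated correlation. Gap genes fell in 8 of 14, and 8 adjusted over the list alone, with gt at -4.32 ± 0.41 (adjusted p = 2.95e-07; adjusted p = 0.0805 with an estimated correlation). Bearded and E(spl) genes fell in 5 of 10 and rose in 1, also when adjusted over the list alone, with Ocho at -4.48 ± 0.41. The list had adjusted p = 4.77e-05 (0.074 with an estimated correlation). Neurogenic ectoderm genes fell in 5 of 12, and 5 adjusted over the list alone, with sog at -4.15 ± 0.41 and SoxN at -3.44 ± 0.48. The list had adjusted p = 5.57e-05 (0.132 with an estimated correlation). Terminal and gut genes fell in 4 of 6, and 5 adjusted over the list alone, with byn, a hindgut factor, at -4.92 ± 0.81. The list had adjusted p = 0.000167 (0.0868 with an estimated correlation). Hox genes fell in 4 of 8 and rose in 1, also when adjusted over the list alone, with Ubx at -7.19 ± 0.87, Dfd at -4.36 ± 0.50 and lab at 3.62 ± 0.79. The list had adjusted p = 0.00922 (0.194 with an estimated correlation). Mesoderm genes fell in 6 of 15, and adjusted over the list alone 7 fell and 1 rose, with sna at -3.17 ± 0.70 and twi at -1.91 ± 0.49. The list had adjusted p = 0.0186 (0.371 with an estimated correlation). Sex readouts fell in 2 of 5, and 3 adjusted over the list alone, with lncRNA:roX1 at -3.43 ± 0.45 (adjusted p = 0.0382; adjusted p = 0.0868 with an estimated correlation).

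Apoptosis and DNA damage genes went the other way at NC13-14: of 9 in the p53 list 5 rose and 1 fell, also when adjusted over the list alone. The p53 genes as a list had a median of 2.58 and adjusted p = 0.00697, and adjusted p = 0.141 with an estimated correlation. The cell death activators hid (2.69 ± 0.46) and rpr (3.24 ± 0.58) and the stress factor Xrp1 (4.01 ± 0.50, adjusted p = 5.11e-07) rose, and egr, the TNF ligand, fell by 2.18 ± 0.48. The ribosomal protein list was called with 2 members lower and 2 higher of 87, and 1 lower adjusted over the list alone, RpS5b being at -1.07 ± 0.19 and at -0.83 with scaling on the list itself. Ribosomal protein genes as a list had a median of -0.21 and adjusted p = 0.018, and adjusted p = 0.757 with an estimated correlation. Outside the lists, Nepl4, which codes for a neprilysin-like protein, was at least 829-fold lower with 0 counts over the 4 CRY2-ZLD libraries, and Ac78C, an adenylyl cyclase gene, fell by 7.58 ± 0.48. Both were also lower without light, at -2.32 and -1.13 against wild type NC10-14 and NC13-14 averaged. In all, 851 genes fell and 792 rose at NC13-14, and 866 and 825 with the 2 parts of the library set as a term. Ribosomal protein scaling shifted the median of all genes by 0.21 and gave 572 lower and 931 higher (38.1% lower against 51.8%), and a fit of only these 8 libraries gave 1395 and 1558.

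Light during NC14 alone, the cycle of collection, lowered several early zygotic genes as well. The gene slam fell by 2.37 ± 0.37 (adjusted p = 2.02e-05; n = 4 each), ftz by 6.44 ± 0.78, gt by 2.99 ± 0.39 and sog by 3.37 ± 0.40. Pair-rule genes fell in 8 of 10, with hry at -4.49 ± 0.56 and prd at -3.68 ± 0.56, and 8 adjusted over the list alone. The list had adjusted p = 2.24e-08 (0.109 with an estimated correlation). Dorsal ectoderm genes fell in 11 of 16, with tld at -4.82 ± 0.49, and 11 adjusted over the list alone (adjusted p = 2.24e-08; adjusted p = 0.0573 with an estimated correlation). Bearded and E(spl) genes fell in 5 of 10, with Tom at -3.58 ± 0.33 and Ocho at -3.72 ± 0.39, and 5 adjusted over the list alone. The list had adjusted p = 3.61e-06 (0.0831 with an estimated correlation). Cellularization genes fell in 5 of 9, and 5 adjusted over the list alone, with bnk at -4.54 ± 0.68 and Nrt at -2.41 ± 0.21. The list had adjusted p = 9.13e-06 (0.133 with an estimated correlation). The members halo (-1.54 ± 0.42, adjusted p = 0.0101) and Z600 (-1.30 ± 0.38, adjusted p = 0.0164) did not pass in all settings. Without single libraries, halo was -1.12 (adjusted p = 0.0596) without wild-type replicate 1, Z600 was -1.13 (adjusted p = 0.0654) without CRY2-ZLD replicate 3 and -1.17 (adjusted p = 0.0524) without wild-type replicate 3. Ribosomal protein scaling left them at -1.03 (adjusted p = 0.0904) and -0.79 (adjusted p = 0.186).

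Gap genes fell in 4 of 14 at NC14, and 4 adjusted over the list alone (adjusted p = 0.00176; adjusted p = 0.262 with an estimated correlation). X counting genes fell in 4 of 8, and 5 adjusted over the list alone, with sisA at -4.47 ± 0.61 (adjusted p = 0.00276; adjusted p = 0.109 with an estimated correlation). Neurogenic ectoderm genes fell in 4 of 12 and rose in 1, 5 and 1 adjusted over the list alone, with SoxN at -2.94 ± 0.47. The list had adjusted p = 0.00251 (0.262 with an estimated correlation). Hox genes fell in 4 of 8 and rose in 1, 5 and 1 adjusted over the list alone; Dfd was at -5.53 ± 0.54 and lab at 4.14 ± 0.81, and Ubx was at least 280-fold lower, with 0 counts over the 4 CRY2-ZLD libraries. The list had adjusted p = 0.00343 (0.211 with an estimated correlation). Of the p53 list 5 of 9 rose, 6 with 1 lower adjusted over the list alone, with hid at 3.22 ± 0.47, Xrp1 at 3.32 ± 0.49, skl at 2.72 ± 0.57 and rpr at 2.38 ± 0.55. The p53 genes as a list had a median of 2.38 and adjusted p = 0.00276, and adjusted p = 0.148 with an estimated correlation. Segment polarity genes rose in 3 of 8, and 5 adjusted over the list alone, with mid at 5.20 ± 0.90. Segment polarity genes as a list had a median of 1.82 and adjusted p = 0.00657, and adjusted p = 0.211 with an estimated correlation. Ribosomal protein genes fell in 44 of 87, and adjusted over the list alone 72 fell and 1 rose, a direction that scaling on these genes takes out. RpS3 went from -0.66 ± 0.15 to -0.11 (adjusted p = 0.46) and RpS5b from -1.35 ± 0.19 to -0.82. Ribosomal protein genes as a list had a median of -0.60 and adjusted p = 2.42e-10, and adjusted p = 0.355 with an estimated correlation. The panel genes sna (-0.78 ± 0.65), Kr (-0.76 ± 0.33), kni (-0.58 ± 0.40), twi (-1.28 ± 0.49) and Sxl (-2.25 ± 0.92) did not pass at NC14. The same held for nullo (-0.24 ± 0.69; 0.13 without CRY2-ZLD replicate 3 and 0.69 without wild-type replicate 1), sc (-0.42 ± 0.61; 0.01 without wild-type replicate 4) and hb (-0.27 ± 0.51; 0.03 with ribosomal protein scaling). In all, 919 genes fell and 742 rose at NC14. Ribosomal protein scaling shifted the median of all genes by 0.45 and gave 462 lower and 1472 higher (23.9% lower against 55.3%), and a fit of only these 8 libraries gave 420 and 289.

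After light during NC10-12, which was off again for NC13 and NC14, many early zygotic genes did not pass at collection, while many other transcripts differed. Values for slam (-0.41 ± 0.35), ftz (-0.95 ± 0.61), sog (-0.71 ± 0.36), bnk (0.66 ± 0.58), halo (-1.04 ± 0.41) and sna (-0.75 ± 0.65) did not pass (n = 4 each). Others were lower, Nrt at -1.41 ± 0.21 (adjusted p = 6.29e-06), sisA at -2.92 ± 0.56 (adjusted p = 0.000181) and run at -1.97 ± 0.40 (adjusted p = 0.000335). But sisA was also lower than wild type without light (-1.77 ± 0.50) and did not pass against unlit CRY2-ZLD (-1.11 ± 0.53). The gap gene gt (-0.02 ± 0.36) did not pass either and turned to 0.13 and 0.01 without CRY2-ZLD replicates 3 and 4 and to 0.01 and 0.04 without wild-type replicates 2 and 3. By list, 2 of 9 cellularization genes were lower and 1 higher, 6 and 3 of 16 dorsal ectoderm genes, 4 and 1 of 8 X counting genes, 5 and 0 of 15 mesoderm genes, and 4 and 0 of 10 Bearded and E(spl) genes. None of these 5 lists was called (lowest adjusted p = 0.0605, mesoderm). The only called list was the pair-rule genes, of which 5 of 10 fell, and 5 adjusted over the list alone, with opa at -2.46 ± 0.62 and prd at -2.05 ± 0.52. This list had a median of -1.10 and adjusted p = 0.0257 (0.69 with an estimated correlation). Among single genes that rose were nullo (FBgn0004143, chromosome X, 7049476 to 7050321) by 4.94 ± 0.79 (adjusted p = 2.04e-05), from 4.63 ± 2.60 to 143 ± 30.2 CPM (SD), sc by 3.20 ± 0.64 and zen2 by 3.25 ± 0.67. Some maternal transcripts rose, such as bcd (FBgn0000166, chromosome 3R, 6755842 to 6759466), the anterior determinant, by 7.14 ± 1.24, twe, a meiotic and early mitotic phosphatase, by 3.09 ± 0.59 and Clamp, a chromatin-binding activator, by 1.74 ± 0.24. Without the 5 libraries bcd was at 2.46 (adjusted p = 0.042) and twe at 2.19 (adjusted p = 0.016). The rise of smg (2.60 ± 0.53) was 1.67 (adjusted p = 0.0072) without CRY2-ZLD replicate 3, and 0.19 (adjusted p = 0.756) without the 5 libraries. As lists, maternal RNAs had 4 lower and 6 higher of 18 (adjusted p = 0.619), and maternal activators 1 lower and 4 higher of 10, with 5 higher adjusted over the list alone (adjusted p = 0.127). Among single genes that fell were srp, a GATA factor of the blood and gut lineages, at -3.99 ± 0.65, ush at -3.75 ± 0.65 and stumps, an adaptor of FGF signalling, at -4.49 ± 0.82. In the p53 list 2 fell and 5 rose of 9, 3 and 6 adjusted over the list alone (adjusted p = 0.275), with Xrp1 at 3.33 ± 0.49, p53 at 1.64 ± 0.29 and skl at 3.25 ± 0.58.

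The panel genes Sxl, zen and eve passed at NC10-12 without holding in all settings. Sxl was at -3.65 ± 0.97 (adjusted p = 0.00437) and at -3.29 (adjusted p = 0.0848) without the 5 libraries. The gene zen was at 1.48 ± 0.50 (adjusted p = 0.0208), and at 1.27 (adjusted p = 0.0686) without CRY2-ZLD replicate 4, 1.43 (adjusted p = 0.0558) without wild-type replicate 1 and 1.41 (adjusted p = 0.0507) without wild-type replicate 3. The gene eve was at -1.15 ± 0.39 (adjusted p = 0.0205), and at -0.91 (adjusted p = 0.0872) without CRY2-ZLD replicate 3, -1.0 (adjusted p = 0.074) without CRY2-ZLD replicate 4 and -0.89 (adjusted p = 0.146) with ribosomal protein scaling. In all, 1567 genes fell and 1613 rose at NC10-12. The maternal transcripts were highest in CRY2-ZLD replicates 3 and 4, where smg reached 1688 and 838 CPM, and without the 5 libraries 967 genes were lower and 917 higher. Ribosomal protein scaling shifted the median of all genes by 0.21 and gave 887 lower and 1757 higher (33.5% lower against 49.3%).

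**Figure D2:**
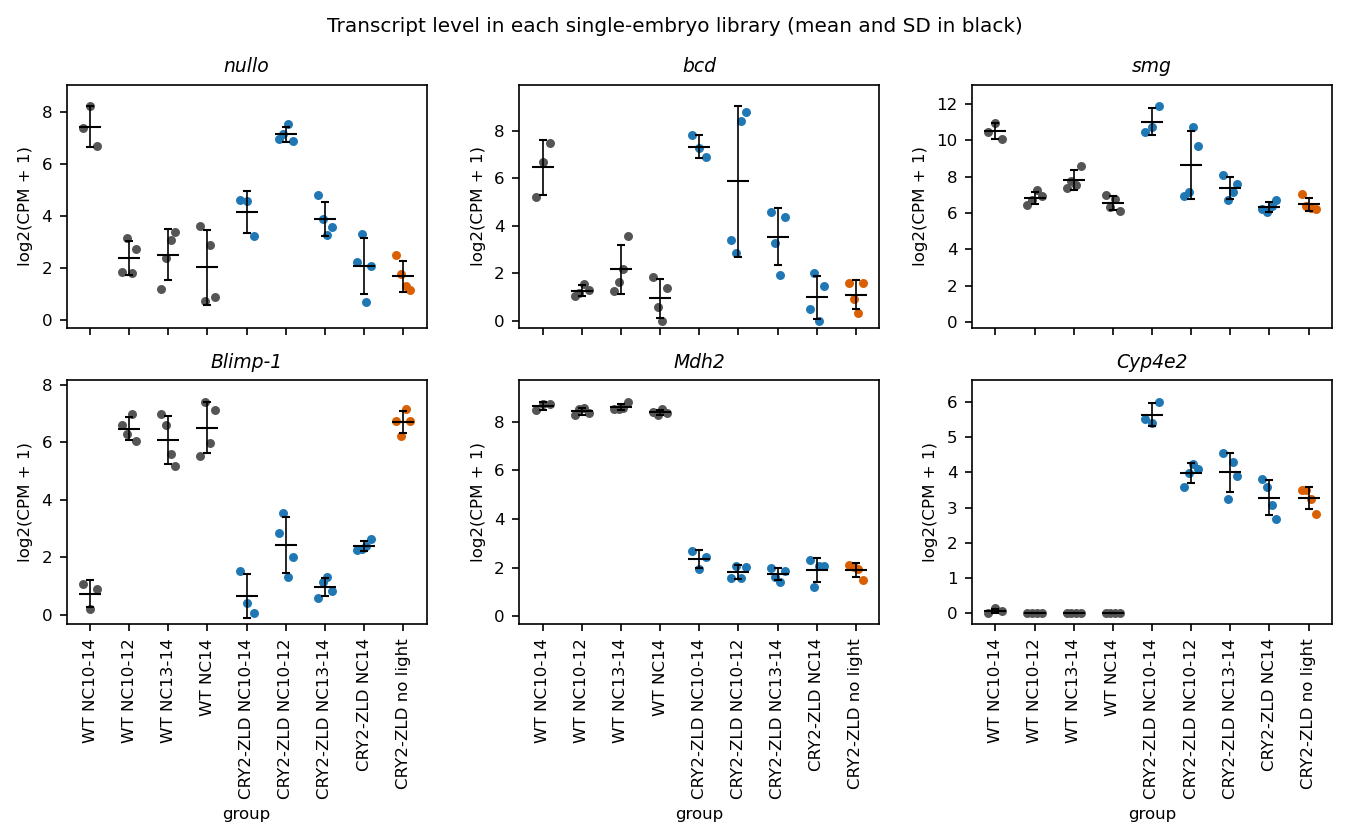
Levels of nullo, bcd, smg, Blimp-1, Mdh2 and Cyp4e2 in each of the 34 libraries, as log2(CPM + 1) on the y axis and the 9 groups on the x axis; points are libraries, and bars are the group mean ± SD. Mdh2 averaged 345 CPM in wild type NC10-12 and 2.77 in CRY2-ZLD without light, and smg 1498 CPM in wild type NC10-14 and 236 in wild type NC13-14.

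The lists not yet described were not called against wild type in any window. Heat shock genes included 1 lower and 5 higher of 12 at NC14 (list adjusted p = 0.142 at NC14 and 0.0966 at NC13-14, where 2 rose); Hsp68 rose by 2.53 ± 0.49 at NC13-14. At NC14 the call on Hsp70Bb (3.29 ± 0.88) was lost without CRY2-ZLD replicate 3 (2.56, adjusted p = 0.0505), and that on Hsp70Bc (4.72 ± 1.25) too (1.78, adjusted p = 0.298). In the oxidative stress and light damage list 2 of 10 fell and 1 rose at NC10-14 (list adjusted p = 0.507), with Keap1, a sensor of oxidative stress, at -1.58 ± 0.29, and 3 fell at NC10-12 (list adjusted p = 0.275, the lowest of the windows). Pole cell markers had 0 lower and 2 higher of 7 at NC14 (list adjusted p = 0.0757, the lowest of the windows) and 0 and 1 at NC10-14 (list adjusted p = 0.32). The germline gene vas rose by 1.36 ± 0.40 at NC13-14 (adjusted p = 0.0147), but not without wild-type replicate 2 (1.22, adjusted p = 0.0606). It rose by 1.38 ± 0.39 at NC14 (adjusted p = 0.0131), but not without CRY2-ZLD replicate 2 (0.96, adjusted p = 0.0992) or wild-type replicates 3 (1.19, adjusted p = 0.0565) or 4 (1.16, adjusted p = 0.053). Markers of differentiated tissues of later embryos had 0 lower and 0 higher of 8 at NC14 (list adjusted p = 0.472, the lowest of the windows). Of 16 follicle cell and yolk protein genes only 2 had enough counts to be tested, and neither Yp3 (-0.06 ± 0.83) nor Cp18 (1.72 ± 1.15) passed at NC10-14. Yp3 turned to 0.29 with ribosomal protein scaling, to 0.14 and 0.43 without CRY2-ZLD replicates 1 and 4 and to 0.38 without wild-type replicate 4, and Cp18 turned to -0.14 without CRY2-ZLD replicate 1.

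**Figure D3:**
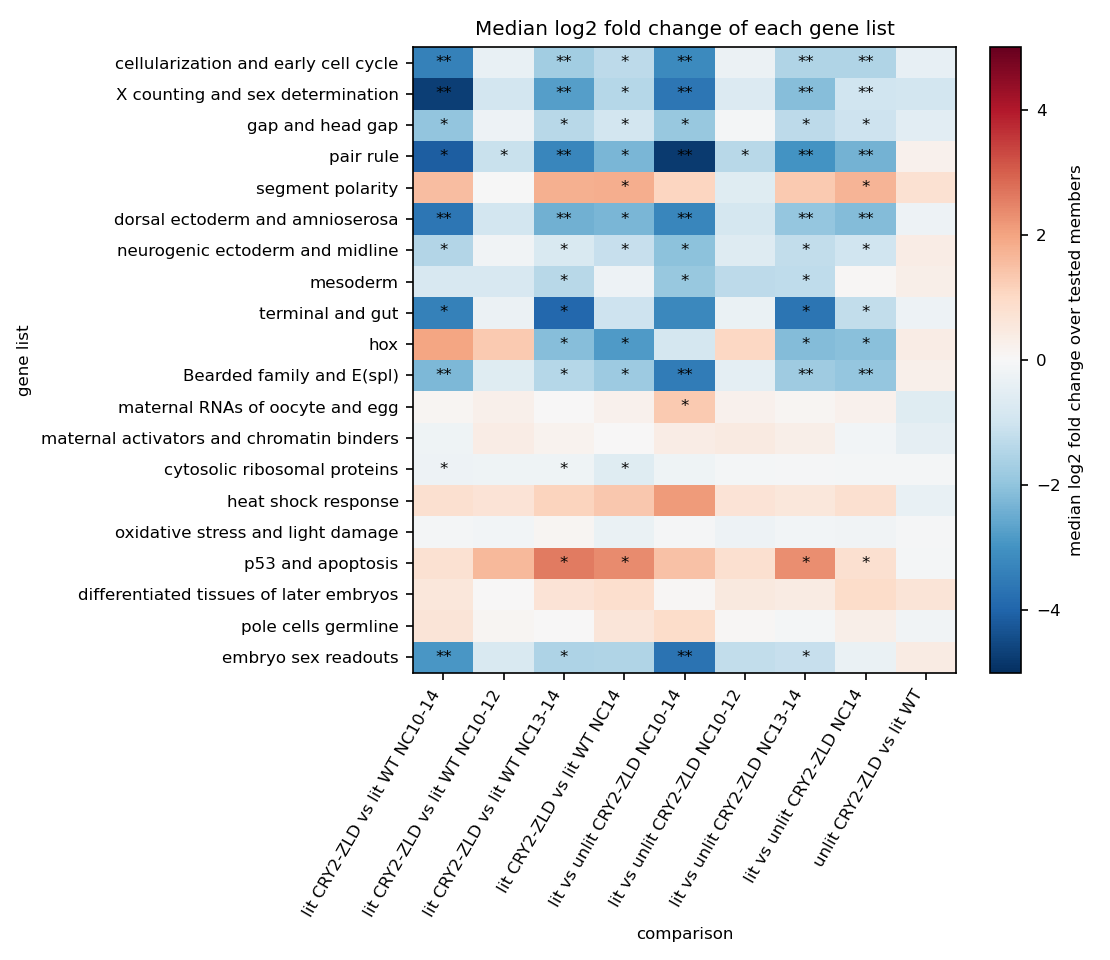
Median log2 change of the tested members of each gene list (vertical) in each comparison (horizontal), as colour; 1 star marks a list called with the preset correlation and 2 stars a list also called with an estimated correlation. The cellularization list had a median of -3.37 at NC10-14 and -1.73 at NC13-14.

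Wild type itself differed between windows, NC10-14 from NC13-14 in 1764 genes, with nullo higher at NC10-14 by 5.15. The difference of the CRY2-ZLD minus wild-type changes between windows takes in such shifts as well as the effect of light. Between NC10-14 and NC10-12 this difference passed for 834 genes, 461 lower and 373 higher at NC10-14. All 9 cellularization genes were among the lower, also when adjusted over the list alone, with slam at -3.56 and bnk at -7.28, and ftz (-8.00), gt (-4.83), sog (-3.62), zen (-6.95) and eve (-3.43) were lower as well. Cellularization genes as a list had a median of -2.97 and adjusted p = 6.89e-20, and adjusted p = 0.00193 with an estimated correlation. X counting genes were lower in 4 of 8, and 4 adjusted over the list alone (adjusted p = 6.71e-07; adjusted p = 0.00236 with an estimated correlation), with upd1 at -9.49 ± 1.05. The count was 512 without CRY2-ZLD NC10-12 replicate 4, 506 without CRY2-ZLD NC10-14 replicate 4, 479 without wild type NC10-12 replicate 1, 477 without wild type NC10-14 replicate 2, 311 with ribosomal protein scaling and 434 without the 5 libraries. Of 100 regroupings, some swapping windows in 1 genotype, 5 gave as many, the real one included.

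Between NC10-12 and NC14 the difference passed for 462 genes, 178 lower and 284 higher at NC10-12. The genes ftz (5.49), bnk (5.20), gt (2.97), zen (3.81) and nullo (5.18) were higher at NC10-12, as was sog (2.66), though not with ribosomal protein scaling (2.55, adjusted p = 0.0513). No list that was called here held with an estimated correlation (lowest adjusted p = 0.315 with an estimated correlation). The count was 964, 177 and 218 without CRY2-ZLD NC10-12 replicates 1, 3 and 4, 225 and 305 without CRY2-ZLD NC14 replicates 1 and 3, 196 without wild type NC10-12 replicate 1 and 260 without wild type NC14 replicate 1. It was 90 with ribosomal protein scaling, which shifted the median of all genes by -0.25, and 101 without the 5 libraries.

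Between NC10-14 and NC13-14 the difference passed for 95 genes, 44 lower and 51 higher at NC10-14, and in 92 with the 2 parts of the library set as a term. Cellularization genes were lower in 3 of 9, and 7 adjusted over the list alone, with term at -2.24 ± 0.43. Cellularization genes as a list had a median of -1.61 and adjusted p = 1.84e-11, and adjusted p = 0.0374 with an estimated correlation. The X-linked gene sc was lower by 4.64, but not without wild type NC10-14 replicate 2 (-3.90, adjusted p = 0.0598). The count was 156, 190 and 43 without CRY2-ZLD NC10-14 replicates 1, 2 and 4, 49 and 59 without wild type NC13-14 replicates 1 and 2, and 37 with ribosomal protein scaling; 7 of 100 regroupings gave as many.

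Between NC13-14 and NC14 the difference passed for 16 genes, 11 lower and 5 higher at NC13-14, among them tutl, a neuronal adhesion gene (-3.54), and btsz, an epithelial actin organiser (-2.83). With ribosomal protein scaling, which shifted the median of all genes by -0.25, edgeR called 0 (adjusted p = 0.0638 for both), with 509 genes at an unadjusted p under 0.05, while DESeq2 called 28 and limma-voom 8 under the same scaling. With their own scaling those tools called 63 and 19. The X counting list, with 0 of 8 called and 2 lower adjusted over the list alone, was called (median -1.23, adjusted p = 0.000174; adjusted p = 0.0401 with an estimated correlation). The count was 9 and 10 without CRY2-ZLD NC13-14 replicates 3 and 4, 6 without CRY2-ZLD NC14 replicate 1, 8, 9 and 9 without wild type NC13-14 replicates 1, 2 and 3, and 6 and 10 without wild type NC14 replicates 3 and 4.

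The windows shared many of their lower genes. NC10-14 and NC13-14 shared 513, where independent sets of their sizes would share 64.5. NC13-14 and NC14 shared 523 against 82.2, and the other 4 pairs shared 424 to 594. The largest Fisher's exact p of the 6 pairs was 3.56e-169, two-sided, across genes, which are not independent replicates. Across genes the log2 changes correlated with r = 0.74 between NC10-14 and NC13-14 and r = 0.56 between NC10-12 and NC14. The 302 genes lower in all 4 windows included 155 that were also lower in CRY2-ZLD without light than in wild type, and of the 155 higher in all 4 windows 112 were also higher there. These comparisons share wild-type libraries: at NC13-14 294 lower and 301 higher genes were also called in the unlit comparison, where independent calls would share 128 and 132. With wild type split between them, the 2 splits shared 138 and 123 lower genes (21.8 and 12.7 if independent) and 96 and 89 higher ones (7.3 and 4.1).

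The second control was CRY2-ZLD without light, which shares genotype and stock with the lit embryos. Against it 3560 genes differed at NC10-14 (1623 lower, 1937 higher), 2678 at NC10-12 (1369 and 1309), 1245 at NC13-14 (610 and 635) and 352 at NC14 (245 and 107). The unlit libraries are in the first library set, so at NC10-12 and NC14 light is confounded with library set, here and in the counts below of genes that differ from both controls. The early zygotic genes ftz, tld, sog and Nrt were lower in lit embryos here too. The gene ftz fell by 9.58 ± 1.06 at NC10-14 (n = 3 and 4), 7.56 ± 0.82 at NC13-14 and 6.66 ± 0.79 at NC14 (n = 4 each). In the same order of windows, tld was at -7.01 ± 0.63, -6.19 ± 0.52 and -4.26 ± 0.47, and sog at -5.07 ± 0.49, -3.75 ± 0.40 and -3.37 ± 0.40. Nrt was at -4.02 ± 0.26, -2.88 ± 0.22 and -2.42 ± 0.21. The cellularization gene nullo was higher instead, by 2.90 ± 0.76 at NC10-14 (adjusted p = 0.00288) and 2.61 ± 0.73 at NC13-14 (adjusted p = 0.0146). At NC13-14 the call was lost without unlit replicates 3 (2.41, adjusted p = 0.0621) or 4 (2.39, adjusted p = 0.0566) or CRY2-ZLD replicate 1 (2.18, adjusted p = 0.068). The gene hb (0.78 ± 0.54 and 0.52 ± 0.51) did not pass. Of the 11 lists called at NC14, 5 held with an estimated correlation. They were the pair-rule (7 of 10 lower), dorsal ectoderm (8 of 16), cellularization (5 of 9) and X counting genes (4 of 8), each with adjusted p = 0.00914, and the Bearded and E(spl) genes (5 of 10, adjusted p = 0.00659). The death activator hid rose against this control as well, by 2.43 ± 0.46 at NC13-14 and 2.20 ± 0.45 at NC14. At NC13-14 rpr rose by 2.99 ± 0.57, and at NC14 it was at 1.82 ± 0.54 and did not pass (adjusted p = 0.0551), but did without CRY2-ZLD replicate 2 (2.03, adjusted p = 0.0401) and with DESeq2 (1.89, adjusted p = 0.00911). At NC13-14 the p53 list had 5 of 9 higher (adjusted p = 0.000496; adjusted p = 0.0572 with an estimated correlation). At NC10-14 maternal RNAs rose in 10 of 18 and fell in 1 (median 1.29, adjusted p = 0.00182; adjusted p = 0.175 with an estimated correlation), with bcd at 7.06 ± 1.25 and smg at 4.67 ± 0.59. An index of transcripts that were higher or lower in wild type NC10-14 than in wild type NC13-14 was 3.49 ± 0.84 (SD, n = 3) in CRY2-ZLD NC10-14 and -0.27 ± 0.43 (SD, n = 4) in unlit CRY2-ZLD. It was also higher than without light by 2.26 at NC10-12 and 1.15 at NC13-14 (exact permutation test, adjusted p = 0.0381 each), so the values of these 3 windows against this control do not separate light from the difference in this index. At NC10-12 ftz (-1.10 ± 0.61) and sog (-0.61 ± 0.36) did not pass, nullo rose by 5.86 ± 0.83, and smg rose by 2.94 ± 0.53 but not without the 5 libraries (0.53, adjusted p = 0.341).

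With the 2 parts of the first library set as a term, which does not separate the sets from each other, the same counts were 3555, 2852, 1256 and 590. At NC13-14 the count was 748 without the unlit replicate 3 and 745 without CRY2-ZLD NC13-14 replicate 1, and at NC10-12 it was 1006 without the 5 libraries. Ribosomal protein scaling shifted the median of all genes by 0.26 at NC10-14 and gave 978 lower and 2115 higher there (31.6% lower against 45.6%). It gave 829 and 967 at NC10-12, 366 and 438 at NC13-14 and 168 and 67 at NC14.

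Genes were then counted that differed in the same direction from both controls, which share the lit CRY2-ZLD libraries, so that an overlap beyond independence is built in. At NC13-14 440 genes were lower than both wild type and unlit CRY2-ZLD and 264 higher, where independent calls would share 54.5 and 52.8. With the lit embryos split between the controls, the 2 splits gave 253 and 243 lower (18.9 and 17.6 if independent) and 106 and 117 higher (15.1 and 19.1). At NC14 227 were lower and 78 higher (23.7 and 8.34 if independent), and the splits gave 121 and 125 lower and 34 and 30 higher. At NC10-12 1045 were lower and 974 higher (225 and 222 if independent), and the splits gave 403 and 364 lower and 449 and 294 higher. At NC10-14 459 were lower and 345 higher (123 and 151 if independent), and no split was run. Over all genes the changes against the 2 controls correlated with r = 0.51 at NC10-14, 0.66 at NC10-12, 0.60 at NC13-14 and 0.68 at NC14, where data simulated without any difference gave 0.53, 0.50, 0.48 and 0.50 through the shared libraries. The covariances were 1.67, 1.38, 1.23 and 1.49, against 0.34, 0.26, 0.25 and 0.26 in the simulated data. In the 3 late windows together 151 genes were lower than both controls, 73 of them also at NC10-12, and 24 were higher, 11 of them also at NC10-12. The genes ftz, slam, gt, sog and tld were lower than both at NC10-14, NC13-14 and NC14. The higher count was 158 without CRY2-ZLD replicate 4 and 181 without each of wild-type replicates 1 and 4 at NC10-14. At NC13-14 it was 174 without unlit replicate 3 and 151 and 175 without CRY2-ZLD replicates 1 and 4, and at NC14 49 and 45 without unlit replicates 2 and 3 and 37 without CRY2-ZLD replicate 3.

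**Figure D4:**
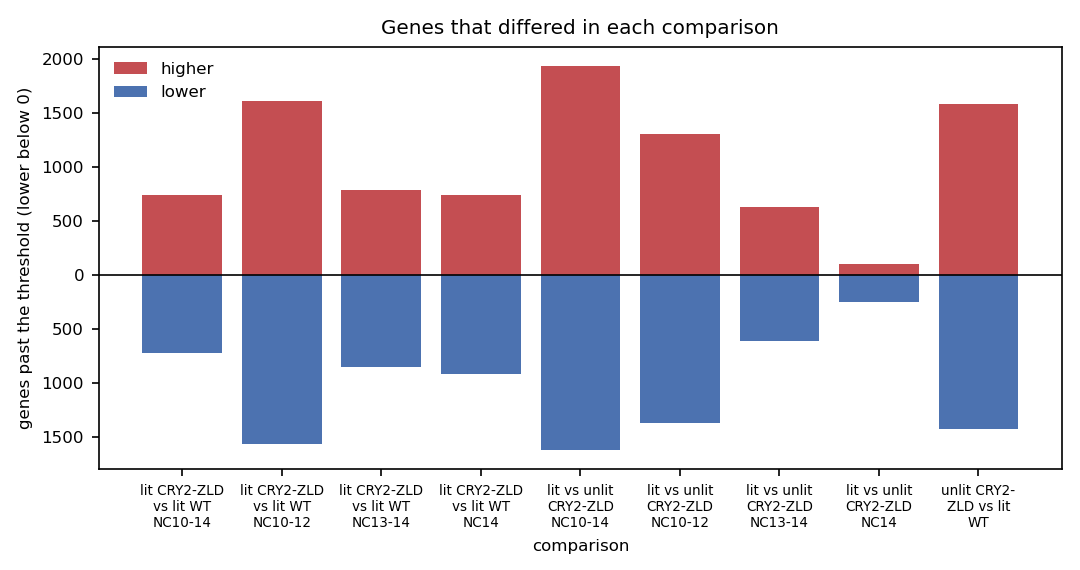
Number of genes lower and higher (vertical axis, genes) in each comparison (horizontal axis), of 9519 tested; bars start at 0. At NC10-12 1567 genes were lower and 1613 higher than in wild type, and at NC14 245 were lower and 107 higher than in unlit CRY2-ZLD.

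CRY2-ZLD without light was set against wild type with light in the same library set (NC10-14 and NC13-14 averaged; n = 4 against 3 and 4), a comparison in which stock and light both differ. Wild type NC10-14 carried high early and maternal transcripts, so values are also given against wild type NC13-14 alone, a reference chosen after the data were seen. Of the early zygotic genes slam (-0.76 ± 0.32), ftz (0.40 ± 0.53), sog (0.16 ± 0.32), gt (-0.52 ± 0.32) and eve (-0.34 ± 0.34) did not pass, though slam did without the unlit replicate 2 (-0.95, adjusted p = 0.0457) or wild type NC10-14 replicate 2 (-0.93, adjusted p = 0.0243), and sog turned to -0.40 against NC13-14 alone. Lower than the averaged reference were nullo (-3.70 ± 0.73), sc (-2.67 ± 0.60), bnk (-2.44 ± 0.58), hb (-1.78 ± 0.48) and, except without the unlit replicate 4 (-1.29, adjusted p = 0.0623), zen (-1.45 ± 0.46, adjusted p = 0.0166). None of these 5 passed against wild type NC13-14 alone, where nullo was at -1.13 ± 0.72, sc at -0.74 ± 0.62, bnk at -1.59 ± 0.59, hb at -1.08 ± 0.51 and zen at -0.52 ± 0.49. Against wild type NC10-14 alone nullo was at -6.28 ± 0.86 and sc at -4.60 ± 0.70. Genes outside the lists differed most: Mdh2 (FBgn0262559), a mitochondrial malate dehydrogenase, by -7.14 ± 0.29 (adjusted p = 6.39e-18), and the glutathione transferase gene GstE8 by -6.65 ± 0.49. The related GstE10, with 1 count over the 4 unlit libraries, was 1460-fold lower (95% counting interval 261 to 57500). No list was called (lowest adjusted p = 0.144, maternal RNAs, with 7 lower and 1 higher of 18, among them plu at -3.08 ± 0.34 and smg at -2.71 ± 0.50). Against wild type NC13-14 alone plu was at -2.84 ± 0.36, while smg was at -1.38 ± 0.51 and did not pass (adjusted p = 0.0899), and against NC10-14 alone smg was at -4.04 ± 0.58. In all, 1430 genes were lower and 1582 higher, 3052 together with the 2 parts of the library set as a term, 764 against NC13-14 alone and 1693 against all 4 wild-type groups. Ribosomal protein scaling gave 885 lower and 1316 higher (40.2% lower against 47.5%).

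A comparison of wild type NC10-14 with wild type NC13-14 was added after the data were seen, because maternal transcripts were high in the first (log2 changes NC10-14 minus NC13-14; n = 3 and 4). The genes nullo (5.15 ± 0.82, adjusted p = 0.000121), sc (3.86 ± 0.68), zen2 (4.12 ± 0.72), bcd (4.75 ± 1.15), smg (2.67 ± 0.55) and twe (3.32 ± 0.62) were higher at NC10-14. Among those that were lower, Blimp-1, an ecdysone-responsive factor that times development, was at -6.70 ± 0.83, ush at -4.41 ± 0.76, nkd at -4.30 ± 0.71, stumps at -4.0 ± 0.90 and opa at -3.51 ± 0.73. Maternal RNAs were higher in 6 of 18 and lower in 1, heat shock genes higher in 5 of 12, with Hsp68 at 3.03 ± 0.52, and hox genes lower in 4 of 8, with Dfd at -3.26 ± 0.53. Each of these 3 lists had adjusted p = 0.00193, and adjusted p = 0.384 with an estimated correlation. Of the patterning lists, pair-rule genes were lower in 2 of 10 (adjusted p = 0.00751), neurogenic ectoderm genes in 5 of 12 (adjusted p = 0.00751) and mesoderm genes in 4 of 15 (adjusted p = 0.0234), each with adjusted p = 0.47 with an estimated correlation. In all, 761 genes were lower and 1003 higher, 1755 together with the 2 parts of the library set as a term. The total of 1764 was 615 without wild type NC10-14 replicate 2 and 1150 without wild type NC13-14 replicate 1, and ribosomal protein scaling, with a median shift of 0.11, gave 398 lower and 988 higher (28.7% lower against 43.1%).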

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

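The tests of differences between light windows were planned, whereas the tests of the genes constant over windows, of embryo age, of library batch and of embryo sex, and the regroupings of libraries, were set out after the results they measure were seen.

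Without light and in all 4 windows, 267 genes differed from wild type in the same direction (155 lower, 112 higher); Mdh2, for example, averaged 2.34 to 4.24 CPM in the CRY2-ZLD groups and 335 to 400 in the wild-type groups. The tables argue against loss of Zelda function without light as the whole cause. Over the 32 early zygotic list members lower with light at NC13-14, median log2 differences from that wild type were -0.41 unlit and -3.12 lit. The unlit share was a median 11.2% (quartiles 5.88 and 26%), against 90.1% over the 267 genes. The 32 were selected on lit calls and the 267 on unlit ones too, so the contrast of shares is no test. A strain background in linked blocks stays open: 68 of the 267 had another of the set within 50000 bp, where 95% of 1000 draws of as many tested genes had 57 to 95 (median 75). This explanation was narrowed from strain background in general to linked blocks, and its reference changed from light-dependent to tested genes, after its result was seen. Strain differences at single genes stay open as well. Of the 267, 124 had no overlap between the 19 CRY2-ZLD and the 15 wild-type libraries (139 of all tested genes). Selection on the same libraries favours this, so it is no test. Genotype and stock are the same groups, and no unlit wild type was used.

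Transcripts that were high in wild type NC10-14 were also high in CRY2-ZLD NC10-12. An index from the 655 genes higher and 555 lower in wild type NC10-14 than in NC13-14 was 1.99 ± 1.0 (SD, n = 4; 1.12 to 3.0) there and -0.01 ± 0.37 (-0.56 to 0.21) in wild type NC10-12. The difference was 2 (exact permutation p = 0.0286, two-sided, the smallest that 70 arrangements can give, and 0.114 adjusted over the 4 windows). Younger or slower embryos may account for part of the NC10-12 calls, but this stays open. The 2 wild-type groups behind the index have the same labelled stage and differ in light length (5 of 12 heat shock genes were higher at NC10-14), no library of known younger age was used, and the maternal RNA list at NC10-12 had 4 lower and 6 higher (adjusted p = 0.619). Of 1091 genes called both there and between the wild-type groups 1063 went the same way (97.4%), against 261 of 316 (82.6%) at NC14, while over all genes the changes correlated with r = 0.31 and 0.08. Against unlit CRY2-ZLD the index was higher in CRY2-ZLD NC10-14 by 3.75 (3.49 ± 0.84 against -0.27 ± 0.43; exact permutation p = 0.0286, the smallest that 35 arrangements can give, and 0.0381 adjusted over the 4 windows). By the same test it was higher by 2.26 at NC10-12 and 1.15 at NC13-14 (adjusted p = 0.0381 each), and it differed by 0.15 at NC14 (adjusted p = 0.629), NC10-12 and NC14 being in other library sets than the unlit embryos. Of 1439 genes called both there at NC10-14 and between the wild-type groups 1421 went the same way (98.7%), with r = 0.51 over all genes, which leaves younger or slower embryos open there too, beside light itself. The bound of both index tests was tightened to ask for libraries of a known earlier stage after their values were seen. Library batch is argued against as the source of the wild-type difference behind the index, which held 1755 genes with the 2 parts of the library set as a term against 1764, though it held 615 without wild type NC10-14 replicate 2 and 1150 without wild type NC13-14 replicate 1. Whether early loss of Zelda itself slows development, or the embryos were staged differently, stays open and was not tested.

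Sxl, which is low in males, was lower in CRY2-ZLD at NC10-14 and NC10-12, and more male embryos are a candidate explanation. In each of the 4 wild-type groups the library lowest in Sxl was the highest in msl-2, which Sxl represses in females (exact permutation p = 0.00521, one-sided), so more males alone would raise msl-2. It was lower instead (-2.92, adjusted p = 0.0118, and -2.97, adjusted p = 0.00145), though at NC10-14 it did not pass without CRY2-ZLD replicate 2 (-2.68, adjusted p = 0.0518), CRY2-ZLD replicate 4 (-2.54, adjusted p = 0.0769) or wild-type replicate 1 (-2.09, adjusted p = 0.104). As msl-2 was also lower than without light (-3.69 ± 0.81 and -3.19 ± 0.70), a loss of msl-2 with light could hide an excess of males, and sex and light cannot be told apart with 3 or 4 embryos a group. The bound of this test was widened to the unlit comparison after its value was seen, which changed more males at NC10-14 and NC10-12 from excluded to open. At NC13-14, where the Sxl call (-2.98 ± 0.95, adjusted p = 0.0261) was lost without CRY2-ZLD replicates 1, 3 or 4 (-2.94, -2.82 and -2.83) or wild-type replicates 2 or 3 (-2.66 and -2.83), msl-2 differed by -1.54 (adjusted p = 0.111), which leaves the same question open.

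Regroupings of the same libraries excluded chance for wild-type and CRY2-ZLD embryos at NC10-12 (3180 genes, 1486 in the highest other split), NC13-14 (1643 and 9) and NC14 (1661 and 126), in each case with 1 of 35 splits as large, the real one. The same held for genes that differ from both controls at NC10-12 (2019 and 1204), NC13-14 (704 and 8) and NC14 (305 and 40). It held for lit against unlit CRY2-ZLD at NC10-14 (3560 and 1970), NC10-12 (2678 and 576), NC13-14 (1245 and 2) and NC14 (352 and 2), and, with 1 of 100 splits, for unlit CRY2-ZLD against wild type (3012 and 2646). Wild type NC10-14 against NC13-14 (1764 and 888) also had 1 of 35 splits as large. That comparison was chosen because its transcripts had been seen to differ, so its splits do not decide on chance. At NC10-14 the 10 splits are too few for a share under 0.05 (1466 genes, 210 in the highest other; 804 and 204 for both controls). Some splits that swap libraries call many genes, which points to a structure of the samples. Without single libraries the 1764 became as few as 615, and the 1245 as few as 745.

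Differences between windows were called for single genes in each of the 4 tests of this kind. The splits of these tests do not decide on chance. In each test's highest other split, most libraries of 1 genotype and few of the other changed window. Differences between windows alone then enter the count. Between NC10-14 and NC13-14 the difference passed for 95 genes, and 7 of 100 splits gave as many (874 in the highest other). The panel genes nullo (-4.85), halo (-2.85) and sc (-4.64) were among the 95. The call was lost for nullo without CRY2-ZLD NC10-14 replicate 4 (-4.45), wild type NC10-14 replicate 2 (-4.32) or wild type NC13-14 replicate 1 (-4.50), for halo without CRY2-ZLD NC10-14 replicate 4 (-2.39), wild type NC10-14 replicate 4 (-2.50) or wild type NC13-14 replicate 1 (-2.71), and for sc without wild type NC10-14 replicate 2 (-3.90). Between NC10-14 and NC10-12 the difference passed for 834 genes, and 5 of 100 splits gave as many (2496 in the highest other). Among the 834 were nullo (-8.31), bnk (-7.28), slam (-3.56), Z600 (-2.97), halo (-3.78), sna (-4.0), sog (-3.62), zen (-6.95), gt (-4.83), Kr (-2.41), kni (-2.68), hb (-2.92), eve (-3.43), ftz (-8.0) and sc (-9.46). Here sna was lost without CRY2-ZLD NC10-14 replicate 4 (-3.45), and hb without CRY2-ZLD NC10-12 replicate 4 (-2.29), CRY2-ZLD NC10-14 replicates 1 (-2.78) or 4 (-2.54) or wild type NC10-14 replicate 1 (-2.53).

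Between NC10-12 and NC14 the difference passed for 462 genes, and 4 of 100 drawn splits gave as many (1962 in the highest other). This falls under a share of 0.05 by 1 split, without adjustment over the 4 tests of this kind, and does not decide on chance. Without single libraries the count ran from 177 to 964. Among the 462 were zld (1.57), nullo (5.18), bnk (5.20), slam (1.96), sog (2.66), zen (3.81), gt (2.97), ftz (5.49) and sc (3.62). The call was lost for zld without CRY2-ZLD NC10-12 replicate 3 (1.24) or CRY2-ZLD NC14 replicate 1 (1.43), for sc without CRY2-ZLD NC10-12 replicate 3 (2.64), and for slam without CRY2-ZLD NC10-12 replicate 4 (1.76), CRY2-ZLD NC14 replicate 1 (1.71), wild type NC10-12 replicate 1 (1.87) or wild type NC14 replicate 1 (1.43). Between NC13-14 and NC14 the difference passed for 16 genes, and 4 of 100 drawn splits gave as many (409 in the highest other), which does not decide on chance either. These 16 rest on the settings: they were 0 with ribosomal protein scaling (edgeR, with 509 at an unadjusted p under 0.05; 28 called with DESeq2 and 8 with limma-voom under the same scaling, tried after the data were seen). Without single libraries they ran from 6 to 22.

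Single libraries lay far from the other 3 of their group in 16 of 154 groups of values examined, where chance gives about 7.7, or 1 in 20. For the share of counts from mitochondrial large ribosomal RNA this was CRY2-ZLD NC10-12 replicate 3 (6.17%, others 8.17 to 8.51%). For nuclear ribosomal RNA it was CRY2-ZLD NC13-14 replicate 4 (0.377%, others 0.00280 to 0.0109%), CRY2-ZLD NC14 replicate 1 (0.0325%, others 0.00426 to 0.00718%), wild type NC13-14 replicate 4 (8.53%, others 0.00295 to 0.00479%) and wild type NC14 replicate 3 (0.0459%, others 0.00446 to 0.00872%). In CPM, zld was 422 in wild type NC10-12 replicate 2 (others 482 to 489), His2Av 2985 and bnk 16.6 in CRY2-ZLD NC14 replicate 3 (others 2473 to 2540 and 5.06 to 6.46). Likewise halo was 398 and twi 140.2 in CRY2-ZLD NC13-14 replicate 2 (others 221 to 243 and 88.1 to 95.3), and kni 222 in wild type NC13-14 replicate 3 (others 167 to 176). In wild type NC10-12 replicate 3 hb was 768 (others 261 to 285) and Sxl 123 (others 1731 to 2039). In CRY2-ZLD NC13-14 replicate 3 sc was 0.739 (others 1.43 to 1.56), and Sxl was 1071 in unlit replicate 4 (others 96.3 to 185) and 420.5 in CRY2-ZLD NC14 replicate 2 (others 183 to 208).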

How the results depend on the processing

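The alternatives marked here as added, and all of those for genes that differ from both controls and for wild type NC10-14 against NC13-14, were chosen after the data were seen. Of 8948 values of single genes under alternatives, 8584 kept their direction and their side of the threshold, 265 lost their call, 66 gained one and 33 turned sign, none of the 33 past the threshold. Of the counts of genes and lists, 525 alternative values lay within 1.5 times the value reported and 117 did not. The 117 are given below, those without single libraries as part of a range, and the cause of these shifts was not tested. The planned search for the CAGGTAG motif near lower genes, with its other motifs and search windows, was not run, as no genome sequence was used. In simulated data the fit recovered 53.2% of 4-fold and 11.3% of 2-fold changes at NC10-14 and 59.1% and 27.7% at NC10-12.

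Scaling on ribosomal protein genes gave 446 (NC10-14), 887 (NC10-12) and 462 (NC14) genes lower and 1472 (NC14) higher than in wild type, 804 for lit against unlit CRY2-ZLD at NC13-14, and 37, 311, 90 and 0 for the differences NC10-14 to NC13-14, NC10-14 to NC10-12, NC10-12 to NC14 and NC13-14 to NC14. The count of 0 is from edgeR, with 509 genes at an unadjusted p under 0.05; under the same scaling DESeq2 called 28 and limma-voom 8 (both added). The same scaling gave 304 (NC10-14) and 531 (NC10-12) lower than both controls. Fitting only the groups compared gave 393 lower and 281 higher (NC10-14), 1395 and 1558 (NC13-14) and 420 and 289 (NC14), 2170 for lit against unlit at NC13-14, and 498, 216 and 33 for the last 3 differences. Against both controls it gave 240, 691 and 704 lower (NC10-14, NC10-12, NC13-14) and 164 and 539 higher (NC10-14, NC13-14). DESeq2 gave 1127 higher (NC10-14), 537 for lit against unlit at NC14, 257, 1315, 797 and 63 for the 4 differences, and 146 higher than both controls at NC14. With limma-voom the first difference had 56 genes, and with a mean of at least 5 CPM the last had 8.

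No pairing by replicate number was established, so block values stand here alone. The block gave 137 genes for lit against unlit at NC14, 48 and 4 for the first and last difference, and 76 lower and 23 higher than both controls at NC14. With only the groups compared it gave 229 lower and 130 higher (NC10-14), 1322 and 1308 (NC13-14), and 351 and 247 (NC14).

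Leaving out the 5 libraries (added) gave 967 lower and 917 higher at NC10-12, 1006 for lit against unlit at NC10-12, 148, 434 and 101 for the first 3 differences, 1065 between the wild-type groups, 538 higher than both controls at NC10-14, and 470 lower and 273 higher than both at NC10-12. The term for the parts of the library set (added) gave 590 for lit against unlit and 119 higher than both controls, both at NC14, and leaving out mitochondrial and ribosomal RNA genes (added) moved none of the counts of genes by over 1.5 times. A fold of at least 2 beside the threshold gave 603 higher than both controls at NC10-12. Unlit CRY2-ZLD differed from wild type NC13-14 alone in 764 genes and from all 4 wild-type groups in 1693 (added), and the count against wild type NC10-14 alone (added) stayed within 1.5 times. Lists called fell to 5, 0, 4 and 0 with an estimated correlation in camera (NC10-14, NC10-12, NC13-14, NC14; 7, 0, 8 and 6 at an unadjusted p under 0.05), while fry called 9, 9, 13 and 13. Lower genes shared between windows were 284 (NC10-14 and NC10-12), 275 (NC10-14 and NC14), 361 (NC10-12 and NC13-14) and 271 (NC10-12 and NC14) at a threshold of 0.01. Without genes called in the unlit comparison (added) they were 245, 288, 212, 310, 248 and 261 for NC10-14 with NC10-12, NC13-14 and NC14, NC10-12 with NC13-14 and NC14, and NC13-14 with NC14.

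The 33 values that turned sign follow. With ribosomal protein scaling they were zld at NC13-14 (0.02) and NC14 (0.29), His2Av at NC13-14 (0.13) and NC10-12 (0.09), nullo (0.32) and hb (0.03) at NC14, gt at NC10-12 (0.22) and Yp3 at NC10-14 (0.29). At NC14 nullo was also 0.18 with limma-voom, 0.10 and 0.16 with the blocks and 0.06 in thinned counts. Without the 5 libraries His2Av at NC14 was -0.03, and at NC10-12 gt was 0.23 and hb -0.31. Unlit CRY2-ZLD against wild type NC13-14 alone (added) turned sog (-0.40), opa (-0.14) and Dfd (-0.18). Leaving out single libraries gave His2Av -0.17 to 0.01 at NC13-14 (highest without CRY2-ZLD replicate 1) and -0.03 to 0.31 at NC14 (lowest without wild-type replicate 3). It gave nullo at NC14 -0.94 to 0.69, with 0.13 and 0.69 (CRY2-ZLD replicate 3, wild-type replicate 1), and sc at NC14 -0.76 to 0.01 (highest without wild-type replicate 4). At NC10-12 gt was -0.15 to 0.13, with 0.13 and 0.01 (CRY2-ZLD replicates 3 and 4) and 0.01 and 0.04 (wild-type replicates 2 and 3), and kni -0.04 to 0.43, with -0.04 and 0 (CRY2-ZLD replicate 2, wild-type replicate 3). At NC10-14 Yp3 was -1.02 to 0.43, with 0.14 and 0.43 without CRY2-ZLD replicates 1 and 4 and 0.38 without wild-type replicate 4, and Cp18 was -0.14 to 2.37, lowest without CRY2-ZLD replicate 1.

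Leaving out each library in turn gave ranges, lowest to highest. Against wild type, lower genes numbered 521 to 704 (NC10-14), 1226 to 1638 (NC10-12), 694 to 803 (NC13-14) and 708 to 962 (NC14), and higher genes 404 to 868, 1270 to 1654, 559 to 690 and 542 to 880. Lit against unlit CRY2-ZLD gave 2782 to 3520, 1927 to 2904, 745 to 1177 and 237 to 380 in the same order, unlit CRY2-ZLD against wild type 2182 to 2976, and the wild-type groups 615 to 1670. The 4 differences gave 43 to 190, 477 to 1195, 177 to 964 and 6 to 22. Genes lower than both controls numbered 337 to 502, 738 to 1164, 324 to 448 and 176 to 238, and genes higher than both 158 to 411, 657 to 1084, 151 to 261 and 37 to 90.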

Other observations

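The genes and values in this part were chosen after the results were seen, and no test was run on them beyond the comparisons above.

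The gene grh, which codes for a DNA-binding factor of epithelia and stands in the list of maternal activators, was lower in lit CRY2-ZLD than in wild type in all 4 windows, by -3.75 ± 0.46 at NC10-14, -1.55 ± 0.36 at NC10-12, -4.92 ± 0.41 at NC13-14 and -4.18 ± 0.40 at NC14. Against unlit CRY2-ZLD it was at -6.65 ± 0.51, -1.94 ± 0.36, -5.42 ± 0.42 and -4.46 ± 0.40. Without light it was higher than in wild type NC10-14 and NC13-14 averaged (1.70 ± 0.30), but did not pass against NC13-14 alone (0.50 ± 0.35), and in wild type NC10-14 it averaged 47.3 CPM against 250.1 in wild type NC13-14. The T-box gene mid was higher than in wild type by 5.74 ± 1.06, 4.76 ± 0.93, 7.92 ± 1.09 and 5.20 ± 0.90 in the same order of windows, with 31.9 CPM in CRY2-ZLD NC10-12 replicate 3 and 2.68 to 4.24 in the other 3. The egg activation gene plu was lower than in wild type by -1.27 ± 0.39, -2.46 ± 0.35, -3.03 ± 0.36 and -2.74 ± 0.36, and without light by -3.08 ± 0.34, and it was higher in lit than in unlit CRY2-ZLD at NC10-14 (2.05 ± 0.36). Its call against wild type at NC10-14 was lost with ribosomal protein scaling (-1.10, adjusted p = 0.0857) and without CRY2-ZLD replicates 1 (-1.01, adjusted p = 0.127) or 2 (-0.99, adjusted p = 0.112) or wild-type replicates 1 (-1.26, adjusted p = 0.0597) or 4 (-1.22, adjusted p = 0.0699).

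In wild type NC14 replicate 3 mthl8 stood at 22.6 CPM, while it stood at no more than 0.224 in the other wild-type libraries and at 7.34 to 79.4 in the CRY2-ZLD libraries. In the same library Mdh2 stood at 366 CPM and Cyp4e2 at 0, against 1.31 to 5.43 and 5.36 to 63.5 CPM in the CRY2-ZLD libraries. The first 2 principal components of the 34 libraries held 30.1% and 18.8% of the variance.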
